A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

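Total RNA from S. cerevisiae cultures was extracted with hot phenol and cleaned on columns, and biotin-labelled cRNA was made with a 3' IVT kit and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, and tested on the file every array averages 1 over its 10715 probe sets, so that each array had been divided by its own mean. The background correction, the summarisation of probes and the software are not given in the sources used here. Scaling to the mean makes values relative within an array: a change in total RNA per cell cannot be seen, and a few bright genes that rise lower all others slightly.

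Samples were grouped by the labels into 4 CFTR and 7 vector arrays. The vector replicate numbers are those of the labels, and the CFTR numbers follow the order of deposition and name arrays only. Per the labels the control vector carries a GPD promoter and the CFTR plasmid a PGK promoter, so that the plasmids differ by more than the CFTR gene. The vector arrays are marked in the labels as re-analysed. No column was left out.

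Probe sets were named through the platform annotation, matched to the gene table of assembly R64, which served for names and gene order only. Of the probe sets, 5498 matched exactly 1 S. cerevisiae gene, 1746 were named for a gene not in that table, 1 carried several genes and 3470 were unnamed in the annotation. Where several probe sets matched a gene (47 genes), the brightest over the 11 arrays stood for it, which left 5449 genes. The unmatched probe sets had a median log2 level near -3.9, against -0.22 for the matched ones, and served as a measure of background.

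The values were log2-transformed without a floor. The design fixed before the data were examined had set values under 1 to 1, which presumed unscaled intensities; with an array mean of 1 that floor lies above the median probe set of every array and would flatten most of the values, so it was run as an alternative chosen after seeing the data. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene lists and chromosomes were tested with camera at the preset correlation of 0.01, with the correlation estimated per list beside it, and lists also with fry. All 44 lists were fixed before the data were examined and needed at least 4 measured members. List means per array were compared by exact two-sided permutation over the 330 splits into 4 and 7, a test added after seeing the data.

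The genes named were those with the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean level above the 25th percentile of tested genes and all CFTR arrays beyond all vector arrays; a fixed set of genes for stress, plasmid and nutrient markers whatever their p, of which TRP1 was not measured here; and up to 4 members with the smallest p of each list past the threshold and of the UPR, degradation, chaperone, stress, efflux and ion transport lists. Genes named outside this rule are marked as such.

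The fit was tested on simulated data for the CFTR and vector comparison, with the real spread of 5449 genes and 200 of them changed. It recovered 61.2% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2, with 13 false calls among 182. With 1 list raised by 0.5, 1 list passed, the raised one. Both simulations drew genes and arrays independently, with 1 spread per gene for both groups, and held no code ranges or near-copy arrays. The real genes and arrays are not independent, so that these shares do not carry over to the real comparison.

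Alternatives were quantile normalization, median centring, no intensity trend, robust eBayes, array weights, a filter on dim genes (mean log2 level above -1.17, the 95th percentile of unmatched probe sets, leaving 4111 genes), the mean of a gene's probe sets, controls of either code range alone, leaving out each array, and counts of non-overlapping genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.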

Results

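Budding yeast carrying a plasmid for the cystic fibrosis transmembrane conductance regulator (CFTR, a human chloride channel of the ABC transporter family) was compared with yeast carrying an empty vector. RNA abundance was measured on Affymetrix arrays in 11 samples, 4 expressing CFTR and 7 with the vector. All cultures were grown at 26 degrees in selective medium to mid log phase. CFTR with an HA tag was expressed from a PGK promoter. The values are probe set intensities scaled to an array mean of 1, and the 11 arrays had medians between 0.219 and 0.272 over their 10715 probe sets. Levels are given as log2 of the scaled intensity, with SD over arrays, and 5449 S. cerevisiae genes were tested. The series text speaks of biological replicates but does not tie arrays to cultures, so that p-values measure the spread between these arrays, part of which may be technical. Within the vector group, replicates 1 and 2 differed by an SD of only 0.11 across genes (log2), and replicates 5 and 7 by 0.10, against a median of 0.48 over the 21 pairs of vector arrays. Across genes, which are not independent replicates, vector replicate 3 correlated at 0.986 to 0.995 with the CFTR arrays and at 0.952 to 0.974 with the other vector arrays, so that over all genes it sat with the CFTR group. The number of arrays limits the precision.

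The comparison of CFTR with vector asks which yeast genes respond to a foreign membrane protein. UBA1, which encodes the E1 enzyme that activates ubiquitin, rose 2.13-fold, from 1.53 ± 0.17 (SD, n = 7) in the vector arrays to 2.62 ± 0.02 (SD, n = 4) in the CFTR arrays (limma, adjusted p = 0.00024). SSA4, a stress-inducible cytosolic Hsp70, rose 4.50-fold, from -0.23 ± 0.73 to 1.94 ± 0.22 (adjusted p = 0.018). ADE17, an enzyme of purine synthesis, rose 2.81-fold (adjusted p = 0.040), although its CFTR and vector arrays overlapped. GIT1, a glycerophosphoinositol transporter, fell from -0.99 ± 0.53 to -2.45 ± 0.19 (adjusted p = 0.028), a CFTR level within the range of unmatched probe sets, whose 95th percentile was -1.17, so that the size of its fall is uncertain. SUL1, a sulfate permease, was 2.11-fold lower, falling from 2.26 ± 0.18 to 1.19 ± 0.53 (adjusted p = 0.030). AQY2, an aquaporin-like gene named here after its values were seen, fell from -0.18 ± 0.56 to -1.56 ± 0.23 (adjusted p = 0.040), again to within that range, and its CFTR and vector arrays overlapped. These 6 genes are the ones that passed the test with a change of at least 2-fold. Of all 50 called genes, 13 had a group mean under that limit.

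In all, 27 genes rose and 23 fell (limma, adjusted p under 0.05), with absolute log2 fold changes between 0.34 and 2.17. Among genes with a mean level above the 25th percentile and no overlap between the groups, and beyond the chaperone genes described below, the larger rises were in EEB1, an acyltransferase of ethyl ester synthesis (log2 fold change 0.83, SE 0.11), OPI10 (0.83, SE 0.13), MDJ1, a mitochondrial J protein (0.93, SE 0.17), MET28, a transcription factor of sulfur metabolism (0.67, SE 0.11), MAG1, a DNA glycosylase (0.63, SE 0.11, with a vector mean of -1.22), ADE1, of purine synthesis (0.65, SE 0.13), and YDR222W (0.84, SE 0.16). Within the same limits the larger falls, besides SUL1, were in ASH1, the daughter cell repressor of mating type switching (-0.88, SE 0.15), SRL3 (-0.86, SE 0.17), SPL2, a regulator of phosphate uptake (-0.77, SE 0.12), RGL1 (-0.73, SE 0.13), the G1 cyclin CLN2 (-0.63, SE 0.11), YNL058C (-0.61, SE 0.11) and GPI12, of GPI anchor synthesis (-0.58, SE 0.09). PGS1, MCT1, ARK1 and MAF1 fell by 0.42 to 0.48 on the log2 scale. Below the 25th percentile, and named after their values were seen, SMP1 (-0.96, SE 0.19) and SPT14 (-0.76, SE 0.15) fell as well. The sizes of MAG1, PGS1, ARK1, SMP1 and SPT14 are uncertain, since 1 or both group means (both for SMP1) lay under -1.17, the background limit given above. Of the 50 genes, 44 had all 4 CFTR arrays beyond all 7 vector arrays. Over all tested genes 131 lay wholly above and 182 wholly below, where chance alone gives 16.5 in each direction (0.303% of genes). At an unadjusted p under 0.05 there were 989 genes.

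The CFTR arrays carry sample codes 7 to 10 and no vector array does, so that a batch following the codes and the effect of CFTR cannot be told apart. Putting vector replicate 3 in place of CFTR replicate 1, which makes a group of 4 arrays with codes 5 to 9, called 477 genes, more than the 50 of the real groups. The 4 vector arrays of codes 11 to 14 against the other 7 arrays called 1467 (both divisions were chosen after seeing the data). The number of called genes rested on the controls and on single arrays. Against vector replicates 1 to 3 alone, UBA1 was the 1 gene called, and against vector replicates 4 to 7 alone 1466 genes were higher and 927 lower. Without CFTR replicate 1, 2, 3 or 4 the fit called 2, 4, 8 or 4 genes. Without vector replicates 1 to 7, each left out in turn, it called 24, 34, 521, 17, 4, 10 and 4. The 521 are of 5449 genes, the share to set beside the list counts given below for the fit without vector replicate 3. UBA1 passed under each of the 23 alternative settings in which the model was refitted, with log2 fold changes between 0.97 and 1.22 and adjusted p between 2.3e-09 and 0.016.

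Cytosolic chaperones and co-chaperones of the heat shock response had the smallest camera p of the 44 gene lists. Of the 24 measured members of this list, 8 rose over all genes tested and none fell, and 22 rose when adjusted over the list alone. Besides SSA4 these were HSP82, an Hsp90 (log2 fold change 0.96, SE 0.16), CPR6, an Hsp90-binding cyclophilin (0.71, SE 0.09), MBF1 (0.53, SE 0.10), AHA1, an activator of Hsp90 (0.63, SE 0.12), the J protein SIS1 (0.76, SE 0.16), FES1, a nucleotide exchange factor of Hsp70 (0.66, SE 0.14), and HCH1 (0.53, SE 0.11). The mean log2 level of the list was 2.22 ± 0.03 (SD, n = 4) in CFTR and 1.53 ± 0.24 (SD, n = 7) in vector arrays, and an exact two-sided permutation test of these means gave p = 0.0030, the smallest that 330 splits allow (adjusted p = 0.067 over the 44 lists). By camera with the preset correlation the list's adjusted p was 3.7e-25, and the adjusted p = 0.21 with an estimated correlation. Vector replicate 3 stood at 2.06, close to the CFTR arrays, while the other vector arrays lay between 1.40 and 1.59. Without vector replicate 3, 22 of the 24 members passed over all genes tested and the list's camera adjusted p was 0.0012 with an estimated correlation. Since vector replicate 3 had nearly the CFTR level in this list, leaving it out strengthens the list by construction and is no further support. The genes SSA1 and SSA2, and HSP82 and HSC82, are near-identical pairs whose probe sets may share signal, so that their single values are uncertain. HSP104, a disaggregase (0.81, SE 0.18, adjusted p = 0.057), and SSA1 (0.54, SE 0.15, adjusted p = 0.092) did not pass, and the small heat shock protein HSP26 had a log2 fold change of 1.13 with an SE of 0.75.

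**Figure D1:**
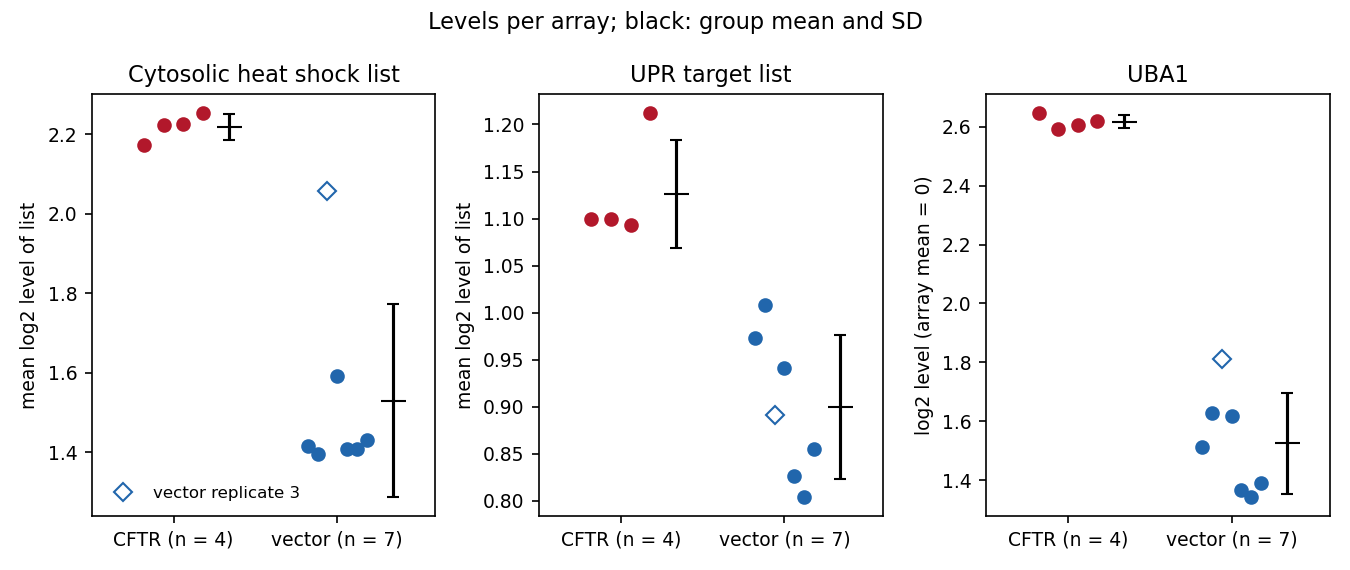
Mean log2 level of the cytosolic heat shock list (left), of the UPR target list (middle) and of UBA1 (right), 1 point per array, with the group mean and SD in black; the vertical axes are on a log2 scale and do not start at 0. Vector replicate 3 (open diamond) is at 2.06 in the heat shock list, close to the CFTR arrays, but at 0.89 in the UPR list and at 1.81 for UBA1, within or nearer the vector arrays.

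Targets of the unfolded protein response (UPR), the transcriptional response to misfolded protein in the endoplasmic reticulum (ER), were higher by a smaller amount. Of 23 measured targets, 1 rose over all genes tested, ULI1 (log2 fold change 0.99, SE 0.15, adjusted p = 0.018), and 9 when adjusted over the list alone. The vector mean of ULI1, -1.85, lay under the background limit of -1.17, so that the size of its rise is uncertain. Among these 9 were ERO1, the ER thiol oxidase (0.48, SE 0.10), KAR2, the ER Hsp70 (0.31, SE 0.07), and ERV29, a cargo receptor (0.32, SE 0.07), whose adjusted p over all genes were 0.054, 0.059 and 0.059. Without vector replicate 3, 8 targets rose over all genes tested, among them these 3 (adjusted p = 0.015, 0.021 and 0.016). The list mean was 1.13 ± 0.06 (SD, n = 4) in CFTR and 0.90 ± 0.08 (SD, n = 7) in vector arrays, with all CFTR arrays above all vector arrays (exact permutation p = 0.0030, adjusted p = 0.067). Camera gave an adjusted p of 1.3e-09, or adjusted p = 0.21 with an estimated correlation. Without vector replicate 3 both were weaker (camera adjusted p = 1.7e-07 and 0.37). More targets were called there, in a fit that called 521 genes in all. HAC1, which encodes the transcription factor of this response (0.20, SE 0.08), PDI1 (0.16, SE 0.10) and DER1 (0.09, SE 0.07) did not pass.

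Proteasome genes were higher by a similar median amount to the UPR targets. Of 37 proteasome genes, 1 rose over all genes tested, PRE6, a core subunit (log2 fold change 0.41, SE 0.08, adjusted p = 0.040), and 13 when adjusted over the list alone. RPN4, the transcription factor of proteasome genes, had a log2 fold change of 0.56 (SE 0.12, adjusted p = 0.054). Without vector replicate 3, 6 of the 37 rose over all genes tested, RPN4 among them (adjusted p = 0.0054). The proteasome list had a median of 0.19, with 32 of 37 members above 0. Its list mean was 1.61 ± 0.02 (SD, n = 4) in CFTR and 1.41 ± 0.12 (SD, n = 7) in vector arrays, with all CFTR arrays above all vector arrays (exact permutation p = 0.0091, adjusted p = 0.10; camera adjusted p = 9.9e-12, adjusted p = 0.47 with an estimated correlation). Vector replicates 1 to 3 had proteasome list means of 1.487 to 1.56, nearer the CFTR arrays (1.591 to 1.627) than replicates 4 to 7 (1.28 to 1.389). The size of the rise thus depended on the controls. Without vector replicate 3 the list's camera adjusted p was 3.4e-10, or 0.48 with an estimated correlation. With all 11 arrays no member of the 28 genes of ER-associated degradation passed, over all genes or over the list alone. Without vector replicate 3, 1 of them rose and 1 fell. The list had a median of 0.08 (camera adjusted p = 0.046, adjusted p = 0.68 with an estimated correlation), and it did not pass against either code range of the vector arrays alone (adjusted p = 0.29 for replicates 1 to 3 and 0.12 for 4 to 7). In that list HRD1, a ubiquitin ligase, had a log2 fold change of -0.06 (SE 0.09), which turned to 0.03 after quantile normalization and 0.01 after median centring, and CDC48, an ATPase that extracts substrates, 0.12 (SE 0.06). The ubiquitin gene UBI4 had 0.19 (SE 0.10, adjusted p = 0.34) and was looked at after the values of UBA1 were seen. SGT2, a co-chaperone that hands tail-anchored proteins to the ER, rose by 0.48 (SE 0.07, adjusted p = 0.018), the 1 member of 29 ER translocation genes to pass with all 11 arrays (3 rose without vector replicate 3).

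Of 23 genes of purine and pyrimidine synthesis, ADE17 and ADE1 rose over all genes tested and 8 when adjusted over the list alone, and vector replicate 3 had a list mean of 1.63 against 1.62 ± 0.10 (SD, n = 4) in CFTR and 1.29 in the other 6 vector arrays. Without vector replicate 3, 8 purine and pyrimidine genes rose over all genes tested, 6 genes of the G2-M and M-G1 phases and 3 of the phosphate regulon fell, and 1 gene of cell wall integrity rose and 3 fell. The purine and the G2-M and M-G1 counts grow by construction, since the array left out had the CFTR level in these lists. The purine list's camera adjusted p was 4.7e-07 (adjusted p = 0.47 with an estimated correlation). Of 16 genes of the phosphate regulon, SPL2 and GIT1 fell, and 5 fell when adjusted over the list alone. PHO84, the high-affinity phosphate transporter, had a log2 fold change of -1.74 (SE 0.44, limma adjusted p = 0.083). Its CFTR arrays were split, at 1.85 and 1.616 in replicates 1 and 4 and at -0.457 and -0.533 in replicates 2 and 3. CFTR replicate 1 lay within the range of the vector arrays (1.639 to 2.795). The phosphate list had a median of -0.47 (camera adjusted p = 0.00024, adjusted p = 0.68 with an estimated correlation). Its camera call was carried by vector replicates 1 to 3 (adjusted p = 3.2e-05 against these alone) and was lost against replicates 4 to 7 (adjusted p = 0.080), whose list means of -0.08 to 0.11 overlapped those of the CFTR arrays (-0.54 to 0.03). Of 28 genes of the G2-M and M-G1 phases, ASH1 fell, and 4 fell when adjusted over the list alone. The list median was -0.24 (camera adjusted p = 5.8e-06, or 0.66 with an estimated correlation). Vector replicate 3 had a list mean of -0.343, within the CFTR arrays (-0.345 to -0.27). The other vector arrays lay between -0.126 and 0.196. Of 29 genes of cell wall integrity, KDX1 fell from -0.86 ± 0.42 (SD, n = 7) to -1.86 ± 0.19 (SD, n = 4; adjusted p = 0.046), a level within the range of unmatched probe sets and with overlap between the groups, so that the size of its fall is uncertain. The cell wall list had an adjusted p of 0.050 by camera, lower in CFTR, and adjusted p = 0.68 with an estimated correlation. Camera's direction, which is relative to the other genes, rested on the controls. The list passed as lower against vector replicates 4 to 7 alone (camera adjusted p = 7.2e-07). It passed as higher against replicates 1 to 3 alone (median 0.02, camera adjusted p = 0.043), where the median of all genes was -0.149. The list means did not turn: the CFTR arrays (2.026 to 2.043) lay below vector replicate 3 (2.048) and the other vector arrays (2.06 or more).

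In the remaining lists past the camera threshold no gene was called by limma with all 11 arrays. Without vector replicate 3, each but the cytosolic ribosomal proteins had 1 or more members called. Other choices of controls also raised the calls over all genes, to 2393 against vector replicates 4 to 7 alone and 1002 without the vector arrays of codes 3 and 4. With all 11 arrays no member passed among 72 mitochondrial ribosomal protein genes (median -0.34) or 48 genes of the TCA cycle and respiration (median -0.29). Nor did any among 128 cytosolic ribosomal protein genes (median 0.11) or 39 general stress genes (median 0.33). The same held for N-glycosylation (median 0.07), COPII and COPI coats (0.06), amino acid synthesis (0.06), thiamine and vitamin B6 (-0.80), pheromone and mating (-0.21) and genes expressed in MATa cells (-0.17). Both MATa list means (-2.75 and -2.55) and the pheromone mean in CFTR (-1.34) lay under the background limit of -1.17, so that the size of these falls is uncertain. Most camera calls of these 10 lists rested on the choice of controls. Against vector replicates 1 to 3 alone, those of mitochondrial ribosomal proteins (adjusted p = 0.16), N-glycosylation (0.37), pheromone (0.20) and MATa genes (0.16) were lost. Camera's direction, which is relative to the other genes, turned up there for respiration and thiamine without passing (0.35 for both). Their medians stayed negative (-0.127 and -0.038), beside -0.149 for all genes. Against vector replicates 4 to 7 alone, the camera calls of general stress (adjusted p = 0.25), amino acid synthesis (0.30), the coats (0.095) and MATa genes (0.085) were lost. The cytosolic ribosomal proteins turned down there (adjusted p = 0.22), and passed as lower with array weights (adjusted p = 0.036). Without vector replicate 3, 16 mitochondrial ribosomal protein genes fell, 5 genes of respiration fell and 1 rose, and 5 general stress genes rose. In the same fit 2 thiamine and vitamin B6 genes rose and 6 fell, and 3 pheromone genes and 1 MATa gene fell. Further, 2 genes of N-glycosylation, 2 of the coats and 3 of amino acid synthesis rose. Of all 5449 genes that fit called 521, 220 higher and 301 lower, so that counts of 1 to 3 members do not set a list apart. In the mean of the mitochondrial ribosomal proteins, CFTR replicate 1 stood at 0.62 and the other CFTR arrays between -0.07 and 0.19, while vector replicate 3 stood at 0.105 and the other vector arrays between 0.276 and 0.71. In that of respiration, CFTR replicate 1 stood at 2.23 against 1.484 to 1.685 in the other CFTR arrays, and vector replicate 3 at 1.601 against 1.985 to 2.275 in the other vector arrays. With an estimated correlation the adjusted p of these 10 lists were 0.68 for mitochondrial ribosomal proteins, cytosolic ribosomal proteins, respiration, general stress, N-glycosylation, amino acid synthesis, thiamine and pheromone, and 0.47 for the coats and MATa genes. In the thiamine and vitamin B6 list the members went both ways when adjusted over the list alone, with 2 higher, SNZ1 (1.29, SE 0.29) and SNO1 (1.24, SE 0.29), of vitamin B6 synthesis, and 6 lower. The size of the SNO1 rise is uncertain, since both its group means (-1.27 and -2.51) lay under the background limit of -1.17. In total 19 of 44 lists passed camera with the preset correlation, 11 higher and 8 lower. Of these, 5 passed in the same direction against either code range of the vector arrays alone (heat shock, proteasome, UPR targets, purine, and G2-M and M-G1), and 14 were lost or turned against at least 1. Of the 5 that held, the purine and the G2-M and M-G1 lists had vector replicate 3 within the range of the CFTR arrays. Of the 44, none passed with an estimated correlation (2 at an unadjusted p under 0.05, the heat shock list and the UPR targets). Fry, which tests whether a list moves on balance, called 2, the heat shock list (adjusted p = 0.0079) and the UPR targets (adjusted p = 0.0094).

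The preset marker genes of the plasmids, of membrane transport and of nutrient supply had no called change against all 7 vector arrays, but several passed against some of them. Transport genes outside this preset group were called, among them SUL1, GIT1 and AQY2, described above. URA3, the marker of pRS426-type plasmids, had a log2 fold change of 0.33 (SE 0.17, adjusted p = 0.34). PGK1 and TDH3, glycolytic genes, had 0.08 (SE 0.12) and 0.04 (SE 0.12); the value of TDH3 turned to -0.02 after quantile normalization. PMA1, the plasma membrane proton pump, had 0.02 (SE 0.08), or -0.05 after quantile normalization. The ABC transporter genes PDR5 (0.15, SE 0.12), YOR1 (0.17, SE 0.12) and YCF1 (-0.23, SE 0.08) did not pass, nor did any of the 23 drug efflux genes (list median -0.07) or 26 ion transport genes (-0.04), lists for which camera's direction was up (adjusted p = 0.95 for both). Without vector replicate 3, 1 drug efflux gene fell, and 2 ion transport genes rose and 1 fell. Among nutrient markers, LEU2 had 0.01 (SE 0.07), HIS3 0.18 (SE 0.19), ADE2 0.16 (SE 0.12), LYS2 -0.14 (SE 0.17) and MET17 0.06 (SE 0.12), and LEU2 turned to -0.04 after quantile normalization. HSP12, a general stress gene, had 0.05 (SE 0.61), with an SD of 1.36 among the 7 vector arrays. Against vector replicates 4 to 7 alone, URA3 (0.59, adjusted p = 0.00054), YOR1 (0.33, adjusted p = 0.0034), PDR5 (0.31, adjusted p = 0.010) and HIS3 (0.44, adjusted p = 0.031) passed as higher. In the same comparison YCF1 (-0.21, adjusted p = 0.042), HSP12 (-0.92, adjusted p = 0.0074), MET17 (-0.11, adjusted p = 0.041) and TDH3 (-0.13, adjusted p = 0.045) passed as lower. Against vector replicates 1 to 3 alone none of these 8 passed, and URA3 (-0.01), YOR1 (-0.04), PDR5 (-0.06) and HIS3 (-0.17) turned. URA3 also passed without vector replicate 3 (0.44, adjusted p = 0.0495). With array weights URA3, YOR1, PDR5, YCF1, HIS3, ADE2, HSP12 and TDH3 passed. Passing in these fits sets no gene apart: of 5449 genes, array weights called 3310, and the fit against vector replicates 4 to 7 alone called 2393. Genes of MATa cells had a mean level of -2.75 ± 0.09 (SD, n = 4) in CFTR and -2.55 ± 0.08 (SD, n = 7) in vector arrays, genes of MATalpha cells 2.39 ± 0.06 and 2.32 ± 0.31, and genes of meiosis and sporulation -2.84 ± 0.06 and -2.79 ± 0.05. None of the 16 nuclear chromosomes passed as a set by camera (smallest unadjusted p = 0.087, so 0 at an unadjusted p under 0.05, smallest adjusted p = 0.77), and 0 passed with an estimated correlation. Chromosome medians of the log2 fold change lay between -0.08 and 0.01.

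The vector arrays carry sample codes in 2 ranges, 3 to 5 (replicates 1 to 3) and 11 to 14 (replicates 4 to 7), on both sides of the CFTR codes 7 to 10, and these were compared with each other. Between the ranges 1476 genes differed, 372 higher and 1104 lower in codes 11 to 14, which is 27.1% of the genes tested, and 108 of them by at least 2-fold. The balance of directions went with an offset of vector replicates 1 and 2, whose tested genes had median log2 levels of 0.05 and 0.10, against -0.31 in vector replicate 3 and -0.32 to -0.28 in replicates 4 to 7. The median difference of all genes was -0.19 as deposited, -0.035 after quantile normalization (681 higher and 840 lower) and 0.06 after median centring (721 higher and 545 lower). The following genes were named after their values were seen. Higher in codes 11 to 14 were BIO5, a transporter of biotin precursors, by 28.6-fold (adjusted p = 0.00053; its level of -2.85 in codes 3 to 5 is under the background limit, so that this size is uncertain), BIO3, a biotin synthesis enzyme, by 8.58-fold (adjusted p = 0.00053), VHT1, the biotin transporter, by 5.19-fold (adjusted p = 0.0022), and THI7, the thiamine transporter, by 10.6-fold (adjusted p = 0.00047). So were ZPS1 by 7.06-fold and ZAP1, the zinc-responsive regulator, by 3.37-fold (adjusted p = 0.00047 and 0.0023). PHO11, an acid phosphatase, was 4.20-fold lower (adjusted p = 0.00070). THI7 stood at -0.79 ± 0.25 (SD, n = 4) in the CFTR arrays, -0.85 ± 0.21 (SD, n = 3) in codes 3 to 5 and 2.55 ± 0.36 (SD, n = 4) in codes 11 to 14. ZPS1 stood at 2.83 ± 0.46 in CFTR, 0.76 ± 0.28 in codes 3 to 5 and 3.58 ± 0.22 in codes 11 to 14.

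**Figure D2:**
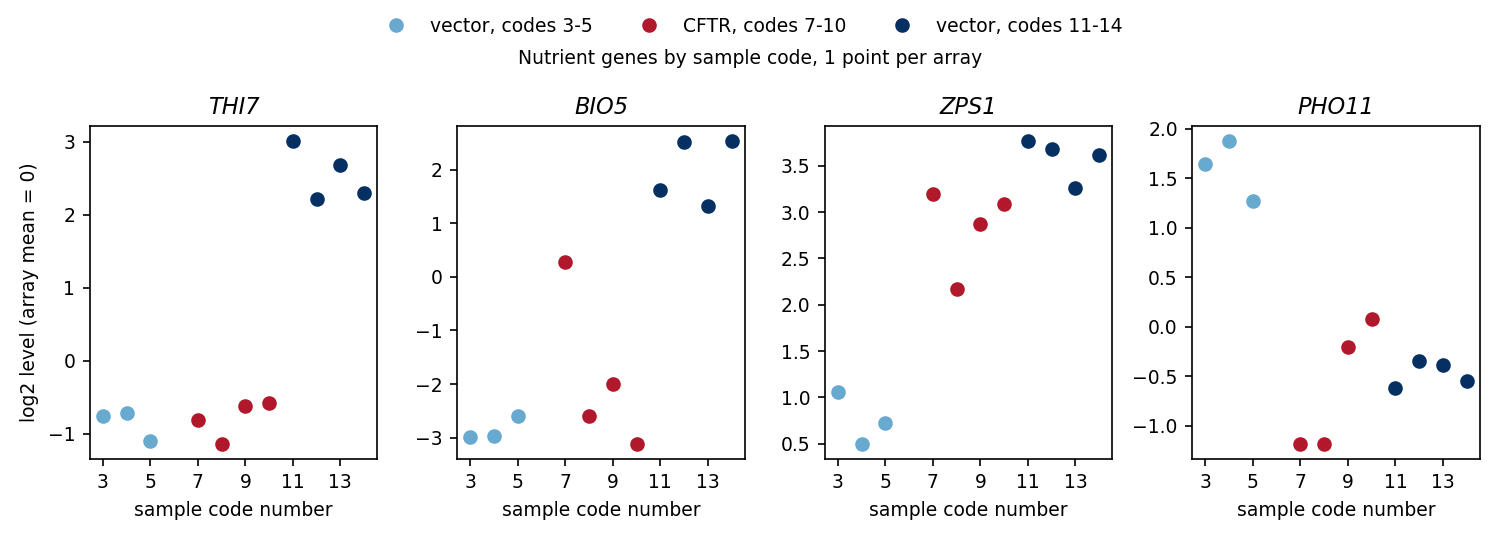
Log2 level of THI7, BIO5, ZPS1 and PHO11 against the sample code, 1 point per array, with vector arrays in blue (codes 3 to 5 light, 11 to 14 dark) and CFTR arrays in red. THI7 in the CFTR arrays (-0.79 ± 0.25) sits with codes 3 to 5, while ZPS1 (2.83 ± 0.46) sits between the code ranges.

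In the gene lists of this comparison of controls, by camera with the preset correlation, the thiamine list (8 of 16 members higher and 2 lower, adjusted p = 8.3e-07), the zinc regulon (7 of 13 higher, adjusted p = 3.2e-08) and the TCA cycle and respiration (18 of 48 higher, 1 lower, adjusted p = 1.5e-14) were higher in codes 11 to 14, and the phosphate regulon (8 of 16 lower, adjusted p = 0.0080) was lower. With an estimated correlation their adjusted p were 0.85, 0.55, 0.68 and 0.85. The smallest p was that of the cytosolic ribosomal proteins, higher in codes 11 to 14 with 3 of 128 members called (adjusted p = 3.8e-20, or 0.85 with an estimated correlation). The proteasome list was lower in codes 11 to 14, with 19 of 37 members called, 2 of them higher (adjusted p = 0.019, or 0.92 with an estimated correlation). The heat shock list did not pass (adjusted p = 0.31). The number of genes called changed with single arrays, to 167, 147 and 3866 without vector replicates 1, 2 and 3, and to 902, 300, 368 and 228 without vector replicates 4 to 7.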

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

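The tests of explanations in this part were chosen after the values were seen. In each group, the array farthest from its neighbours was compared with the group's range; of 86 groups of values examined, 11 had such an array, where chance gives about 4.3. Vector replicate 3 was that array in 9 of them.

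Vector replicate 3 stood apart from the other vector arrays in the mean log2 level of the cytosolic heat shock list (2.06, others 1.44), of the TCA cycle and respiration (1.6, others 2.12) and of amino acid synthesis (2.41, others 2.18). It also stood apart in SSA4 (1.32, others -0.48), OPI10 (0.75, others 0.12), CPR6 (2.19, others 1.79), RGL1 (-0.03, others 0.64), GPI12 (0.31, others 0.68) and PGS1 (-1.05, others -0.70). Among CFTR arrays, replicate 4 was apart in the UPR target list (1.21, others 1.10) and replicate 1 in the ER translocation list (1.36, others 1.42).

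The pattern weighed here is that vector replicate 3 carries nearly the heat shock level of the CFTR arrays, within a wider likeness: over all genes its closest array was CFTR replicate 3 (r = 0.995 across genes), and it lay nearer the CFTR mean than the mean of the other 6 vector arrays in 28 of the 50 called genes. A CFTR culture under a vector label goes with that likeness. The UPR targets argue against it: their mean in vector replicate 3 lay 0.20 below the lowest CFTR array, 3.49 SDs of the CFTR arrays. By the same yardstick its heat shock mean of 2.058 also lay below the lowest CFTR array (2.174, SD 0.033), so that the yardstick alone does not part these lists. Against the other 6 vector arrays, vector replicate 3 lay within their range in the UPR list (0.804 to 1.008) and above it in the heat shock list (1.397 to 1.592). UBA1, at 1.81 against 2.59 in the lowest CFTR array, also goes against such a culture. It is 1 gene, picked by its p in a fit that counts this array as vector, which favours a low value here. In the fit without this array UBA1 passed as well (limma adjusted p = 3.7e-05). CFTR RNA mixed into the array would give both lists a like share of the CFTR difference. The median share it reached was 0.71 over 22 of 24 heat shock genes and 0.25 over 11 of 23 UPR targets, a difference of 0.458. The permutation p = 0.0016 treats genes of 1 array as independent, which they are not (estimated correlation 0.433 and 0.169), so that it is too small. The shares go against mixing but do not exclude it. Array scaling is argued against by the heat shock mean after quantile normalization, which still lay 0.444 above the highest other vector array (SD of those 6 arrays 0.09). A state shared with the CFTR arrays stays open: across 3244 genes with little difference between groups, its deviations correlated with those of the CFTR mean at r = 0.296, against -0.118 to 0.161 for the other vector arrays, in a test revised after a first form on CFTR codes 7 to 9, with unequal references, had favoured this explanation. The bounds of 0.1 and 0.3 for that test were also written after the data were seen, and no biological explanation was tested, since the design gives none for a single vector array.

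Of the 5217 probe sets matched to no single S. cerevisiae gene, which the comparisons do not use, 13 passed the threshold between CFTR and vector, 12 higher and 1 lower. The brightest of the 12 in the CFTR arrays went from -0.40 ± 0.38 (SD, n = 7) in vector to 0.65 ± 0.10 (SD, n = 4) in CFTR arrays (limma adjusted p = 0.018), with vector replicate 3 at 0.39. The lower one went from 1.33 ± 0.39 to 0.47 ± 0.14 (limma adjusted p = 0.048). The genes of both are not named in the annotation used here.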

How the results depend on the processing

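The floor of 1, planned as the main setting, was made an alternative after seeing the data. It called 28 genes, 17 of them among the 50 of the main fit. The floor at the background median, the exact test of list means and the fit without the vector arrays of codes 3 and 4 were chosen after seeing the data. The planned floor at 32 was not run, as no value reaches it. No paired analysis was possible because the CFTR labels carry no replicate numbers. The counts of 27 genes higher, 23 lower and 6 changed at least 2-fold became 116, 84 and 12 with quantile normalization, 105, 68 and 14 with median centring, 1941, 1369 and 78 with array weights, 1, 0 and 0 against vector replicates 1 to 3 only, and 1466, 927 and 70 against vector replicates 4 to 7 only. Without the vector arrays of codes 3 and 4 they were 669, 333 and 25, and with values under 1 set to 1 the lower and 2-fold genes were 7 and 2. Genes with all CFTR arrays above or below all vector arrays numbered 131 and 182. Leaving out each array gave 2 to 220 higher, 0 to 301 lower and 1 to 30 changed 2-fold, the highest each time without vector replicate 3. The cause was not tested. The other settings (no intensity trend, robust eBayes, dim filter, mean of probe sets, floor at the background median) kept these counts within 1.5 times. The 19 lists became 0 with an estimated correlation, 2 with fry and 0 by the exact test of list means (10 at an unadjusted p under 0.05), and 16 to 24 elsewhere. The 0 chromosomes stayed 0 throughout. The 1476 genes between control codes became 4253 with array weights, 262 with the floor of 1 and 147 to 3866 when 1 vector array was left out.

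Some lists (camera's direction, with the list's median) and genes (log2 fold change) turned; the cause was not tested. Past the threshold in the turned direction were cell wall integrity, the zinc regulon and histones against vector replicates 1 to 3 (adjusted p = 0.043, 0.00011 and 0.0010), HSP12, TDH3, MET17 and glycolysis against replicates 4 to 7 (0.0074, 0.045, 0.041 and 0.030), HSP12, TDH3 and cytosolic ribosomal proteins with array weights (0.00085, 0.025 and 0.036), and glycolysis without the vector arrays of codes 3 and 4 (0.013). Against vector replicates 1 to 3 only, these were cell cycle histones (0.173), cell wall integrity (0.022), the zinc regulon (0.285), hexose transport (0.043), respiration (-0.127), thiamine (-0.038), vacuolar sorting (-0.145), ion transport (-0.18), gluconeogenesis (-0.025), RNA polymerase III (-0.204), meiosis (-0.122), HIS3 (-0.168), PDR5 (-0.06), URA3 (-0.014) and YOR1 (-0.039). Against vector replicates 4 to 7 only, these were cytosolic ribosomal proteins (-0.012), glycolysis (-0.088), sulfur amino acids (-0.022), maltose genes (0.037), HSP12 (-0.923), LEU2 (-0.049), MET17 (-0.106), PGK1 (-0.081), PMA1 (-0.065) and TDH3 (-0.126). Without the vector arrays of codes 3 and 4, these were cytosolic ribosomal proteins (-0.014), glycolysis (-0.077), sulfur amino acids (-0.026), maltose genes (0.06), ribosome biogenesis (0.085), translation factors (0.031), mannoproteins (0.013), HSP12 (-0.693), LEU2 (-0.012), MET17 (-0.09), PGK1 (-0.067), PMA1 (-0.057) and TDH3 (-0.101). With array weights, these were cytosolic ribosomal proteins (-0.03), glycolysis (-0.069), sulfur amino acids (-0.087), translation factors (-0.004), maltose genes (0.066), HSP12 (-0.948), LEU2 (-0.018), LYS2 (0.075), MET17 (-0.087), PGK1 (-0.072), PMA1 (-0.026) and TDH3 (-0.12). With quantile normalization, these were sulfur amino acids (0), glycolysis (0.008), RNA polymerase III (0.009), translation factors (-0.017), MATalpha genes (-0.032), maltose genes (0.01), HRD1 (0.032), LEU2 (-0.043), PMA1 (-0.049) and TDH3 (-0.015). With median centring they were histones (0.065), meiosis (0.035), maltose genes (-0.003) and HRD1 (0.013); without the intensity trend, meiosis (-0.04); with the dim filter, drug efflux (-0.031); with the floor at the background median, meiosis (-0.034). With the floor of 1, drug efflux, ion transport, MATa, meiosis and galactose genes turned, each with a median of 0.

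When 1 array was left out, LEU2 ranged from -0.036 to 0.069, HSP12 from -0.262 to 0.283, PMA1 from -0.02 to 0.045, TDH3 from -0.028 to 0.081 and MET17 from -0.007 to 0.097. The medians of lists that turned ranged from -0.051 to 0.017 for histones, -0.111 to 0.005 for drug efflux, -0.06 to -0.009 for ion transport, -0.406 to -0.142 for the iron regulon, -0.118 to -0.013 for maltose genes, -0.06 to -0.002 for meiosis and -0.031 to 0.075 for RNA polymerase III. Over the settings that did not leave out arrays singly, the values of named genes kept their direction and side of the threshold in 1111 cases, were weaker in 50, stronger in 222 and turned in 28. When arrays were left out singly, they kept both in 1033 cases, were weaker in 223, stronger in 49 and turned in 15. Genes wholly under the floor of 1 have no value there.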

Other observations

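The tests of splits into other groups were set before their results were seen; those on UBA1, on the control codes and on divisions that follow the sample codes or exchange vector replicate 3 came after. Among lists not described above, the G1-S genes had a mean level of -0.51 ± 0.06 (SD, n = 4) in CFTR and -0.40 ± 0.06 (SD, n = 7) in vector arrays (exact permutation p = 0.012, adjusted p = 0.11 over 44 lists). The hexose transport list had -0.86 ± 0.07 and -0.66 ± 0.21 (exact permutation p = 0.12, adjusted p = 0.34). Against vector replicates 1 to 3 alone the median log2 fold change of its members turned to 0.04. The list means of these vector arrays (-0.72, -0.864 and -0.956) overlapped those of the CFTR arrays (-0.909 to -0.751). Of 13 mitochondrial chaperone genes, MDJ1 and HSP78 rose; HSP78, named after its values were seen, had a log2 fold change of 0.98 (SE 0.20, limma adjusted p = 0.048), but stood at 1.98 in vector replicate 3 against 2.04 ± 0.05 (SD, n = 4) in CFTR. The iron regulon was at 1.31 in vector replicate 4 and between -0.49 and 0.06 in the other 10 arrays. General stress genes had a list mean of 0.29 and 0.31 in vector replicates 1 and 2, and 0.89 or more in every other array.

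Of 100 divisions of the 11 arrays into 4 and 7, the real one and 99 drawn at random, only the real one called as many as 50 genes, and the highest of the others called 0; the same held for the 6 genes changed at least 2-fold (1 of 100, highest other 0). Chance is excluded by that count for random divisions only, since most of these mix the ranges of sample codes, which differ strongly, and none held 3 CFTR arrays with vector replicate 3. Of the 4 divisions that exchange a CFTR array with vector replicate 3, run after seeing the data, the exchange with CFTR replicate 1 called 477 genes, 28 of them at least 2-fold, and the other 3 called 0. Of the 8 blocks of 4 arrays next to each other in sample code, codes 5 to 9 are that same exchange, the real groups called 50, codes 11 to 14 called 1467 genes, 63 of them at least 2-fold, and the other 5 called 0. The divisions at codes 5 to 9 and 11 to 14 thus called many more genes than the real groups, which points to a structure of the samples, and the count of 50 alone does not tie the changes to CFTR. With the ranges taken as 3 to 5, 7 to 10 and 11 to 14, none holds both groups, so that no fit within one can be had. The labels name no batches, and these bounds were chosen here. A range of codes 5 to 10 would hold both groups, but with vector replicate 3 as its 1 vector array. There the heat shock list stood at 2.06 in that array against 2.22 in CFTR, and UBA1 at 1.81 against 2.62. For gene lists, 39 of 100 divisions called as many as 19, with up to 24, so that chance is not excluded for the number of lists. Of the 35 divisions of the 7 vector arrays into 3 and 4, only the real one by sample code called as many as 1476 genes, and the highest of the others called 1. Vector replicates 1 and 2, and 5 to 7, are near copies of each other, and divisions that part them lose calls by construction, so that this count excludes chance only if they are separate cultures, which the labels do not say.

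UBA1 had the smallest p of all genes, and 3 explanations of its rise were weighed. A gain of its chromosomal region is argued against by the 10 measured genes on either side, whose median log2 fold change was 0.093, with 0 of 20 called. A response that goes with the heat shock level stays open: in vector replicate 3, which has nearly that level, UBA1 was 0.784 below the lowest CFTR array, but at 1.81 it was the highest of the 7 vector arrays, the other 6 reaching at most 1.63, and this rests on 1 array. A piece of UBA1 on the expression plasmid might raise its probe set alone; the neighbour STE6, which ends towards UBA1 in the gene table of assembly R64, had a log2 fold change of -0.074, and without the plasmid's sequence this cannot be told apart from a response of UBA1 to CFTR. That CFTR itself raised UBA1 is a hypothesis, since the sample codes of the CFTR arrays are also their own.

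The division of the vector arrays by sample code may reflect the medium. Array scaling is argued against, since 72.2% of the 1476 calls were kept after quantile normalization. A difference in thiamine supply is consistent with the thiamine list mean, in which the lowest array of codes 11 to 14 lay 0.533 above the highest of codes 3 to 5, although its called members went both ways, 8 higher and 2 lower, and its adjusted p was 0.85 with an estimated correlation. The CFTR arrays had thiamine list means between -0.70 and -0.42, like codes 3 to 5 (-0.81 to -0.44) and unlike codes 11 to 14 (0.09 to 1.23). This was looked for after THI7 had been seen to differ, so it remains a hypothesis, and a difference in culture density or time of growth stays open and untested.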
